A study of Mus musculus with 6 samples.

How the data were processed

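RNA was taken from the apical region of the lower first molar of C57BL/6 mice at postnatal day 7.5, per the labels' protocols. Tamoxifen, dissolved at 20 mg/ml in corn oil, was injected into the abdomen at postnatal day 3.5 at 1.5 mg per 10 g of body weight. Samples were reported to have RNA integrity numbers above 9, and sequencing was single-end with 75 cycles on a NextSeq500. The genotype label put each library into its group, and the replicate number came from the sample title. The library kit and whether it kept strand are not given in the sources used here, so reads of overlapping and antisense genes may not be separated. Reads were aligned by the submitters with tools that included STAR 2.6.1d and Partek on mm10, per the submitters' processing notes, which do not state the role or order of the tools.

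The authors deposited 2 tables, each with all 6 libraries. The first holds expected counts per gene, that is, estimated read counts that need not be whole, and the deposited file is named for Partek's expectation-maximisation quantification. Of its values, 53.8% were whole within 0.001, and library totals were 21067012, 22533024 and 21079918 for control replicates 2, 3 and 5 and 24255352, 22221197 and 20453247 for mutant replicates 3, 4 and 5. It lists 22287 genes, each with a summed count of at least 10. The annotation is not given in the sources used here. For the genes whose positions are printed below, name, chromosome and start match GENCODE M21, from which their end positions were taken. The second table is the authors' normalized signal for 18665 genes. Its values equal the expected count plus 1 times a single factor per library, within a relative deviation of 7.76e-06, and the 75th percentile of each library is 39.2. It was used for 1 alternative and never for the main tests. Because expectation-maximisation shares reads among near-identical genes, values of multigene families such as the globins and Bglap genes are uncertain for single members.

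Expected counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr by group, which left 17305, and libraries were scaled by TMM, with factors of 0.977, 0.949 and 0.872 for control replicates 2, 3 and 5 and 1.07, 1.04 and 1.11 for mutant replicates 3, 4 and 5. CPM values use these scaled library sizes. Differences were tested with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are mutant minus control, and the SE is the absolute log2 fold change divided by the square root of F. The common biological coefficient of variation was 0.161.

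Gene lists were fixed before the data were examined. Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 on the same fit, adjusted over 34 lists. No list was called when the correlation was estimated from the data. The alternative fry tests whether a list's genes move on balance in a single direction and does not compare them with other genes. The level of a list in a library is the mean of log2(CPM + 1), compared by an exact two-sided permutation test.

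Named genes were chosen by a rule fixed before the data were examined. It took 24 genes listed in advance, the 10 largest risers and 10 largest fallers among called genes and up to 4 members with the smallest p in each list. Risers and fallers needed a mean of at least 5 CPM and libraries of the groups that do not overlap, and unnamed gene models and sex-linked genes were passed over. All 322 called genes had groups that do not overlap, as did 21.3% of all tested genes, where chance gives 10% for 3 against 3. Genes named outside the rule are said to be chosen after their values were seen.

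Replicates of a group differed by far more than counting noise, with a chi-square per degree of freedom of 24.5 to 45.0 for pairs within a group, so no library was a copy of another. The replicate numbers 3 and 5 occur in both groups, which gives 2 pairs that share only a number, and the block on this number is treated as an alternative. Alternatives tried were RLE and upper-quartile factors, library totals alone, no filter, a filter of CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, limma on log2(value + 1) of the normalized table, each library left out in turn, and other thresholds. Terms for Xist, epithelial or erythroid level and a fit without abundant transcripts were added after the data were seen.

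The scripts were tested on simulated data drawn from the real means and library sizes, with 200 genes changed in each of 10 draws of the comparison of mutants with controls. In a median of 17051 genes run, 28.1% of genes changed 1.5-fold were called, 70.4% at 2-fold and 95.5% at 4-fold. Of all calls, 7.59% were unchanged genes, above the nominal 5%. A list of 40 genes shifted by 0.6 log2 units was called by camera (adjusted p = 4.8e-83) and with an estimated correlation (adjusted p = 4.29e-05), and an unshifted list was not (adjusted p = 0.453). The simulation draws genes independently, so it does not test the correlation between genes. Differences below 2-fold were thus often missed at this depth and number of libraries.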

Results

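The transcriptome of the apical part of the lower first molar, where the tooth root forms, was measured by RNA sequencing in mouse pups at postnatal day 7.5. All pups received tamoxifen at postnatal day 3.5. The control group carried Arid1a alleles flanked by loxP sites and no Cre (3 libraries, replicates 2, 3 and 5). The mutant group carried the same alleles and Gli1-CreER, a tamoxifen-inducible recombinase under the control of Gli1, which marks Hedgehog-responsive cells (3 libraries, replicates 3, 4 and 5). Because CreER was present in the mutants only, its effects cannot be told apart from those of Arid1a deletion for any gene or list. Arid1a encodes a DNA-binding subunit of the BAF chromatin remodelling complex. The series title names Arid1a, the zinc finger gene Plagl1 and Hedgehog signalling in connection with cell cycle arrest of root progenitors, so these genes and the cell cycle are described first. The libraries held 20453247 to 24255352 estimated gene counts each, and 17305 genes were tested. The labels do not state whether each library came from 1 animal or from pooled teeth, so p-values measure the spread between these libraries.

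Arid1a was the targeted gene and was lower in each mutant library than in each control library. Its level was 205 ± 3.96 CPM (counts scaled by library size, SD, n = 3) in controls, with values of 210, 202 and 204 in replicates 2, 3 and 5. In the mutants it was 128 ± 7.36 CPM (SD, n = 3), with values of 120, 134 and 130 in replicates 3, 4 and 5. It fell by 0.68 on the log2 scale (SE 0.07, adjusted p = 0.0129, edgeR quasi-likelihood test). The gene lies on chromosome 4 of mm10, from 133679008 to 133756769 on the minus strand, and is protein-coding in GENCODE M21. The counts cover the whole gene, so the level says nothing of which exons were lost or in which cells. Without control replicate 2 the adjusted p was 0.0506, and without control replicate 3 it was 0.0529. Its paralog Arid1b did not pass the test (106 ± 10.2 CPM in controls, 102 ± 2.72 in mutants, SD, n = 3, adjusted p = 0.834). Of the 25 BAF and PBAF subunit genes tested, 2 fell and 0 rose, with the same numbers when p-values were adjusted over the list alone. The other faller was Dpf3, a histone-reading subunit, at 7.95 ± 0.661 CPM in controls and 3.58 ± 0.577 in mutants (log2 fold change -1.15, SE 0.16, adjusted p = 0.0227, SD, n = 3). The list as a set did not pass (camera adjusted p = 0.0940).

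**Figure D1:**
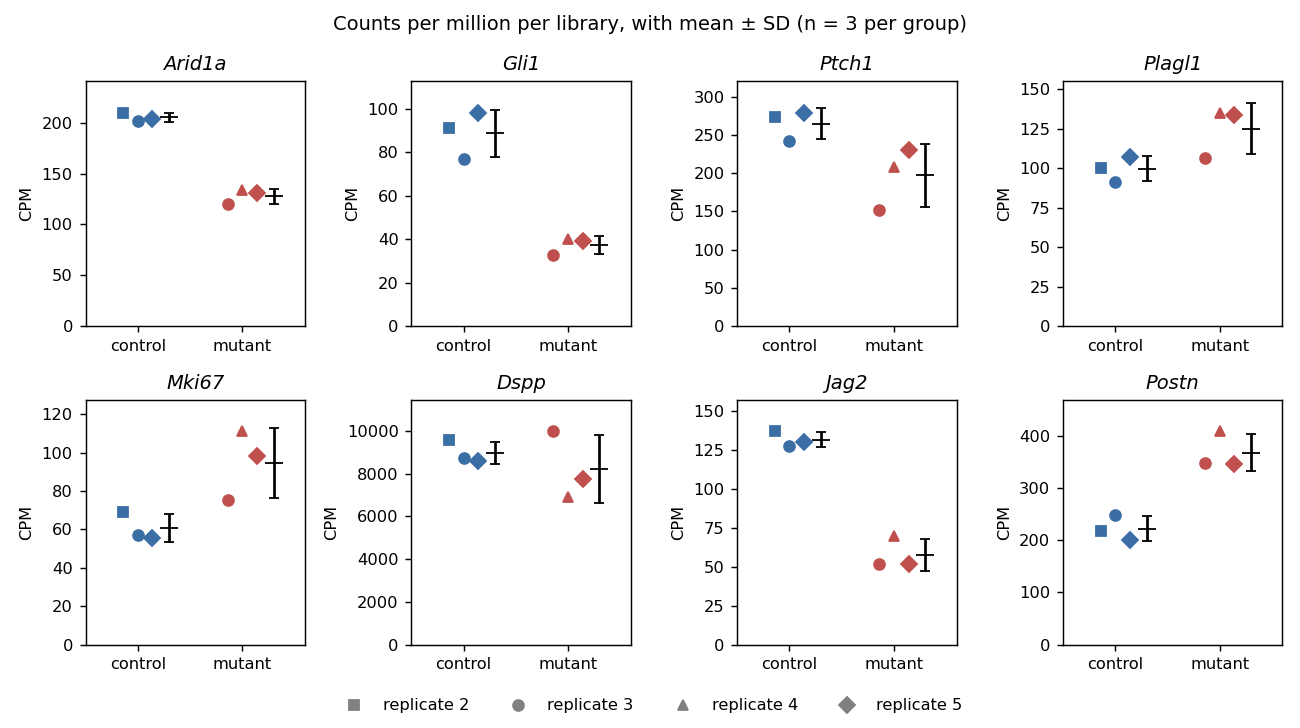
CPM (y axis, from 0) of 8 genes in the 3 control (blue) and 3 mutant (red) libraries, with marker shapes for replicate numbers and black bars for the group mean ± SD. Arid1a, Gli1 and Jag2 were lower and Postn was higher in all 3 mutant libraries and passed the test, whereas Ptch1, Plagl1, Mki67 and Dspp did not pass.

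Across the transcriptome, 114 genes were higher and 208 were lower in the mutants at an adjusted p under 0.05. Among the called genes with a mean of at least 5 CPM, the 10 that rose most included Phox2a, a homeobox gene of autonomic neurons, and Lipm, a lipase gene. They also included Coch, which encodes the matrix protein cochlin, the proteoglycan gene Spock1 and the lipoprotein lipase gene Lpl. Lipm stood at 2.62 ± 0.623 CPM in controls and 12.7 ± 1.84 in mutants (log2 fold change 2.27, SE 0.20, adjusted p = 0.00742, SD, n = 3). Coch stood at 36.0 ± 6.63 CPM in controls and 98.3 ± 8.77 in mutants (log2 fold change 1.45, adjusted p = 0.00742). The others were Opcml, Ndnf, Tenm1, Tac1 and Dpep1, with log2 fold changes from 1.18 for Dpep1 to 1.66 for Opcml. The 10 largest fallers were led by Ctnna2, which encodes an alpha-catenin, and Wnt3a, a Wnt ligand gene. Ctnna2 dropped from 374 ± 74.2 CPM to 64.8 ± 18.2 (log2 fold change -2.53, SE 0.22, adjusted p = 0.00742, SD, n = 3). Wnt3a dropped from 20.6 ± 1.80 CPM to 3.95 ± 1.62 (log2 fold change -2.39, SE 0.29, adjusted p = 0.0150). The others were Sstr2, S100a14, Tesc, Acpp, Pstpip1, Amelx, Klhl33 and Dusp4, with log2 fold changes from -1.83 for Sstr2 to -1.53 for Dusp4.

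The number of calls fell whichever library was left out, by amounts that differed widely, while the directions of the called genes did not change. Such fits have fewer samples. Of the 322 called genes, 124 were lost in all 6 of them. Without control replicate 2, 1 gene was higher and 10 were lower. Without control replicate 3 the numbers were 10 and 23, without control replicate 5 they were 9 and 29, and without mutant replicate 3 they were 105 and 138. Without mutant replicate 4 they were 11 and 61, and without mutant replicate 5 they were 28 and 50. Lipm, Ctnna2 and Pstpip1 were among the 9 genes that remained called in all 6 of these fits. Coch, Spock1, Gli1 and Jag2 were called in 5 of the 6, Arid1a, Acpp, Tac1 and Dkk2 in 4, and Wnt3a, Wnt10a, Sfrp2 and Opcml in 3. Each of the other genes described as called in this section was called in 0 to 2 of the 6 fits. With scaling to library totals alone, the median log2 fold change of all genes moved from 0.01 to 0.21. The calls then split into 411 higher and 109 lower, or 79.0% higher against 35.4%. All 322 called genes kept their sign under that scaling and the other scalings tried.

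Hedgehog pathway genes moved in different directions. Gli1, a transcriptional target and effector of the pathway, fell from 88.6 ± 10.9 CPM in controls to 37.3 ± 3.96 in mutants (log2 fold change -1.25, SE 0.12, adjusted p = 0.00753, SD, n = 3). Gli1 is located on chromosome 10 of mm10 from 127329882 to 127341974. The Gli1 call was lost without control replicate 2 (adjusted p = 0.0506). Ptch1, the main receptor gene, stood at 265 ± 20.0 CPM in controls and 197 ± 40.8 in mutants and did not pass (adjusted p = 0.226). Hhip did not pass either (log2 fold change 0.26, SE 0.28, adjusted p = 0.736), and neither did Smo (adjusted p = 0.517). The 13 Hedgehog targets tested, not all of which are described here, did not pass as a set, with a median log2 fold change of 0.07, a mean of -0.08 and a test direction of lower (camera adjusted p = 0.155). Without control replicate 3 these targets were called lower (median -0.04, camera adjusted p = 0.0295). Without mutant replicate 3 their median was 0.18 (camera adjusted p = 0.622). Of the 18 Hedgehog ligands and transducers, 2 rose, and adjusted over the list alone 2 were higher and 2 lower. The risers were Gas1, a co-receptor gene (83.5 ± 14.4 CPM in controls, 134 ± 5.29 in mutants, adjusted p = 0.0443), and Scube2, which aids release of the ligand (2.06 ± 0.515 and 5.53 ± 1.41 CPM, adjusted p = 0.0465). That list was not called (camera adjusted p = 0.430).

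Plagl1, an imprinted gene that encodes a zinc finger regulator of growth, did not pass the test across all genes. It stood at 99.5 ± 7.95 CPM in controls and 125 ± 16.3 in mutants (log2 fold change 0.33, SE 0.11, adjusted p = 0.210, SD, n = 3), and the libraries of the groups overlapped. The gene lies on chromosome 10 of mm10 from 13060504 to 13131694 on the plus strand. Of the 19 genes of an imprinted growth network tested, which included Plagl1, 1 rose, 0 fell and 18 did not pass. Adjusted over the list alone, 5 were higher and 0 lower. The riser was Peg10, at 16.6 ± 1 CPM in controls and 31.6 ± 6.29 in mutants (adjusted p = 0.0325). Grb10 (log2 fold change 0.49, adjusted p = 0.0520) and H19 (0.50, adjusted p = 0.111) did not pass. The list was called higher (median log2 fold change 0.07, camera adjusted p = 0.00531), with adjusted p = 0.5 with an estimated correlation. The call was lost without control replicate 3 (adjusted p = 0.153) or mutant replicate 5 (0.0817). The list median was 0.22 without control replicate 2, 0.04 without control replicate 3, 0.15 without control replicate 5 and 0.15 without mutant replicate 3.

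Cell cycle genes were higher as groups in the mutants. Of 54 genes active in G2 and mitosis, 52 had positive fold changes, and 4 passed the test across all genes. Adjusted over the list alone, 41 were higher and 1 lower. The median log2 fold change was 0.64, and the list was called higher (camera adjusted p = 1.71e-25). The adjusted p was 0.420 with an estimated correlation. The 4 risers were Nek2, a centrosomal kinase gene, the condensin subunit gene Ncapd2, Cdca3 and Ckap2. Nek2 went from 3.65 ± 0.312 to 7.12 ± 1.21 CPM (log2 fold change 0.96, SE 0.17, adjusted p = 0.0413, SD, n = 3). Cdca3 went from 8.60 ± 0.447 to 14.1 ± 1.55 CPM (log2 fold change 0.71, SE 0.12, adjusted p = 0.0363). The proliferation markers Mki67 (60.7 ± 7.40 CPM in controls, 94.8 ± 18.1 in mutants, adjusted p = 0.0869) and Top2a (45.2 ± 7.54 and 73.6 ± 15.1 CPM, adjusted p = 0.0958) did not pass. Without mutant replicate 3, both passed. Of 43 genes of the G1/S transition, 39 had positive fold changes and 1 passed, as when adjusted over the list alone. It was the ribonucleotide reductase gene Rrm1 (42.8 ± 0.898 CPM in controls, 60.5 ± 3.20 in mutants, adjusted p = 0.0227). This list had a median of 0.33 and was called higher (camera adjusted p = 3.18e-07), with adjusted p = 0.5 with an estimated correlation. Pcna (adjusted p = 0.107) and Ccnd1 (adjusted p = 0.878) did not pass. The level of erythroid markers (mean log2(CPM + 1)) was 7.25 and 6.81 in mutant replicates 4 and 5, while mutant replicate 3 (5.94) lay within the control range of 5.51 to 6.05 (exact permutation p = 0.2). With this level as a term in the model, added after the data were seen, the median of the G2/M genes was 0.33 and their call was kept (camera adjusted p = 1.28e-05). The G1/S median was then 0.13 and that call was lost (camera adjusted p = 0.0937).

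Genes that restrain the cell cycle showed no common direction. Of 20 inhibitors and arrest genes, 2 rose, 1 fell and 17 did not pass, and adjusted over the list alone 4 were higher and 4 lower. The list was not called (camera adjusted p = 0.766). Cdkn2c, which encodes an inhibitor of cyclin-dependent kinases, rose from 11.1 ± 0.403 to 17.8 ± 2.17 CPM (log2 fold change 0.68, adjusted p = 0.0380, SD, n = 3). Gas1, described above, was the other riser. Btg1, an antiproliferative gene, fell from 302 ± 9.90 to 220 ± 20.2 CPM (log2 fold change -0.46, adjusted p = 0.0491). The kinase inhibitor genes Cdkn1a (257 ± 17.4 CPM in controls, 197 ± 25.0 in mutants, adjusted p = 0.131), Cdkn1b (adjusted p = 0.434) and Cdkn1c (adjusted p = 0.866) did not pass. Of 20 p53 target genes, 1 fell and 0 rose (4 higher and 2 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.318). The faller was Aen, an exonuclease gene (log2 fold change -0.42, adjusted p = 0.0453).

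Odontoblast genes, which mark the cells that lay down dentin, were not called as a group in either direction. Of 25 tested, 1 fell, 0 rose and 24 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.584). The dentin matrix gene Dspp stood at 8970 ± 530 CPM in controls and 8216 ± 1587 in mutants (log2 fold change -0.13, SE 0.15, adjusted p = 0.761, SD, n = 3). Col1a1 (adjusted p = 0.938), Dmp1 (0.229), Nfic (0.994), Sp7 (0.348), Dlx5 (0.983) and Runx2 (0.799) did not pass. The faller was Wnt10a, a Wnt ligand gene, at 66.8 ± 2.39 CPM in controls and 43.6 ± 1.24 in mutants (log2 fold change -0.61, SE 0.07, adjusted p = 0.0133).

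Genes of the dental follicle and periodontal ligament, the tissue around the root, were higher as a group. Of 16 tested, 14 had positive fold changes and 2 passed, and 11 were higher and 0 lower adjusted over the list alone. The list median was 0.50, and the list was called higher (camera adjusted p = 6.13e-08), with adjusted p = 0.420 with an estimated correlation. Postn, which encodes the matrix protein periostin, rose from 222 ± 24 to 368 ± 35.5 CPM (log2 fold change 0.73, SE 0.11, adjusted p = 0.0262, SD, n = 3). Igfbp3, an insulin-like growth factor binding protein gene, rose from 385 ± 45.5 to 599 ± 53.4 CPM (log2 fold change 0.64, adjusted p = 0.0389). Of 23 dental mesenchyme progenitor genes, 3 rose and 1 fell (9 higher and 1 lower adjusted over the list alone). The risers were Tac1 (log2 fold change 1.32, adjusted p = 0.0133), the homeobox gene Prrx1 (0.72, adjusted p = 0.0299) and Smoc2 (0.68, adjusted p = 0.0412), and the faller was Gli1. That list was called higher (median 0.19, camera adjusted p = 0.000855), with adjusted p = 0.420 with an estimated correlation. Its median was 0.30 without mutant replicate 3. Msx1 (adjusted p = 0.12) did not pass.

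Collagens and other matrix genes were called higher as a list (38 genes, median log2 fold change 0.15, camera adjusted p = 0.000126), with adjusted p = 0.355 with an estimated correlation. The rotation-based test fry also called it (adjusted p = 0.0368), and this was its sole call among the lists. Of these genes, 2 rose and 0 fell, as when adjusted over the list alone. They were Col14a1, a fibril-associated collagen gene (47.7 ± 6.00 CPM in controls, 97.3 ± 14.9 in mutants, adjusted p = 0.0205, SD, n = 3), and Thbs1 (82.8 ± 10.5 and 144 ± 18.8 CPM, adjusted p = 0.0300). Of 19 osteogenic genes, 1 rose and 0 fell (3 higher and 0 lower adjusted over the list alone), and the riser was Cthrc1 (log2 fold change 0.50, adjusted p = 0.0390). The list was called higher (median 0.10, camera adjusted p = 0.0410), with adjusted p = 0.420 with an estimated correlation. That call was lost without control replicate 2 (0.249), mutant replicate 3 (0.0518) or mutant replicate 4 (0.0637), and with scaling to library totals (0.0565). The osteogenic median was 0.06 without control replicate 5 and 0.05 without mutant replicate 4.

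Among signalling lists, Wnt and Notch genes were called. Of 30 Wnt genes, 3 rose, 2 fell and 25 did not pass (11 higher and 5 lower adjusted over the list alone). The risers were the secreted antagonist genes Dkk2 (17.8 ± 1.75 CPM in controls, 37.2 ± 4.62 in mutants, adjusted p = 0.0133, SD, n = 3) and Sfrp2 (33.5 ± 6.23 and 70.7 ± 1.58 CPM, adjusted p = 0.0163), and Nkd2, an intracellular antagonist gene chosen after its values were seen (adjusted p = 0.0272). The fallers were the ligand genes Wnt10a and Wnt6 (65.5 ± 4.50 and 42.7 ± 2.83 CPM, adjusted p = 0.0227). Axin2, a target gene of the pathway, did not pass (adjusted p = 0.962). The Wnt list was called higher (median 0.10, camera adjusted p = 0.0186), with adjusted p = 0.5 with an estimated correlation. Its call was lost without control replicate 2 (adjusted p = 0.0700) or mutant replicate 4 (0.0830). The Wnt median was 0.00 without control replicate 3, 0.17 without control replicate 5, 0.20 without mutant replicate 3 and 0.01 without mutant replicate 4. Of 16 Notch genes, 1 fell and 0 rose (2 lower and 0 higher adjusted over the list alone). The faller was the ligand gene Jag2, at 132 ± 4.76 CPM in controls and 57.8 ± 10.3 in mutants (log2 fold change -1.19, SE 0.12, adjusted p = 0.0129). The Notch list was called lower (median -0.06, camera adjusted p = 0.0196), with adjusted p = 0.420 with an estimated correlation. This call was lost without control replicate 3 (0.0513) or mutant replicate 3 (0.14), and with scaling to library totals (0.106). The Notch median was -0.02 without control replicate 5, -0.02 without mutant replicate 3 and -0.11 without mutant replicate 4.

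Among enamel genes, Amelx and Mmp20 fell. Of the 12 genes of the ameloblast marker list, these 2 fell and 0 rose (4 lower and 0 higher adjusted over the list alone). The list also holds Dspp, described above as a dentin matrix gene. Amelx, the main enamel matrix gene, stood at 146097 ± 54770 CPM in controls and 48481 ± 12630 in mutants (log2 fold change -1.59, SE 0.30, adjusted p = 0.0470, SD, n = 3). Mmp20, the enamel matrix protease gene, fell from 753 ± 79.0 to 385 ± 55.4 CPM (log2 fold change -0.97, SE 0.13, adjusted p = 0.0205). The Amelx call was lost in each of the 6 leave-one-out fits, with adjusted p values up to 0.123, and the Mmp20 call in 4 of them. Enam (log2 fold change -0.98, adjusted p = 0.0645) and Ambn (-0.78, adjusted p = 0.124) did not pass. The log2 fold changes of Odam, Amtn, Klk4, Slc24a4 and Wdr72, list members expressed at later stages and chosen after their values were seen, were 0.93, 0.79, 0.42, 0.59 and 0.37, and their adjusted p values were 0.540 to 0.835. The list was called lower (median -0.15, camera adjusted p = 0.00265), with adjusted p = 0.420 with an estimated correlation. The call was lost without control replicate 3 (0.0618) or mutant replicate 5 (0.157). The ameloblast median was -0.31 without mutant replicate 3, -0.08 without mutant replicate 4 and -0.07 without mutant replicate 5. Of 17 general epithelial markers, 0 passed, and 3 were lower and 0 higher adjusted over the list alone. That list was called lower (median -0.12, camera adjusted p = 0.0170), with adjusted p = 0.680 with an estimated correlation. Its call was lost without control replicate 3 (0.0993), control replicate 5 (0.149) or mutant replicate 5 (0.644). The epithelium median was -0.31 without control replicate 2, -0.03 without control replicate 5, -0.32 without mutant replicate 3 and -0.01 without mutant replicate 5. Krt14, chosen after its values were seen, stood at 727 ± 91.5 CPM in controls and 742 ± 230 in mutants (adjusted p = 0.968). With scaling to library totals the medians of both lists were above 0 (0.06 and 0.08), below the median of all genes of 0.21. Amelx, Ambn and Enam together took 17.3%, 18.7% and 24.02% of counts in control replicates 2, 3 and 5, and 9.27%, 11.6% and 7.43% in mutant replicates 3, 4 and 5.

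**Figure D2:**
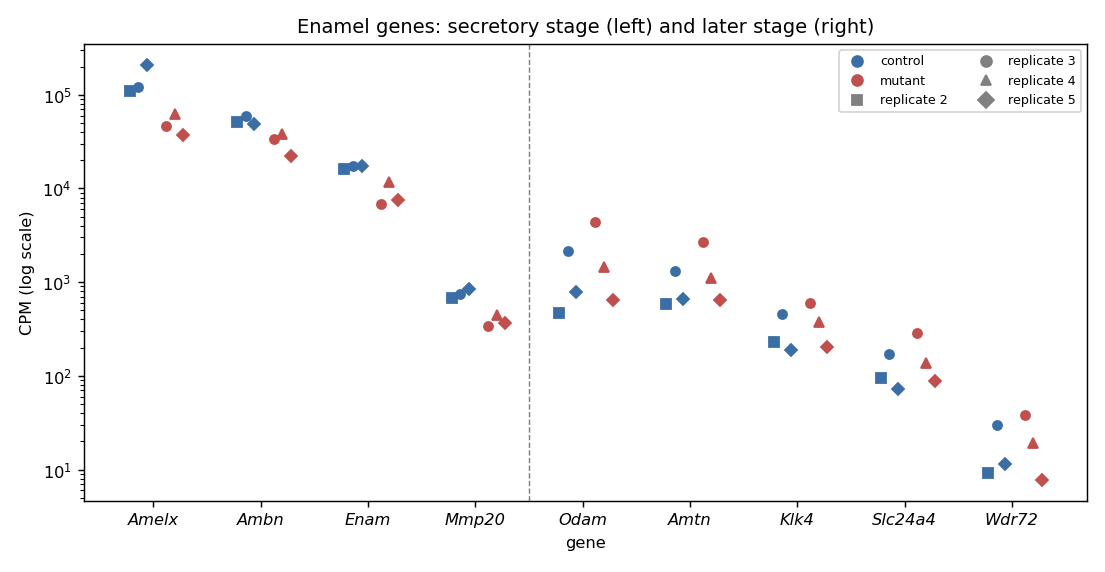
CPM on a log axis of 4 secretory-stage and 5 later-stage enamel genes in the 3 control (blue) and 3 mutant (red) libraries, with marker shapes for replicate numbers. All 3 mutant libraries lie below all 3 controls for Amelx, Ambn, Enam and Mmp20, and the libraries of the groups overlap for the other 5 genes.

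Markers of other cell types were also compared, since the dissected pieces hold more than root mesenchyme. Macrophage and leukocyte markers were called higher (16 genes, 16 with positive fold changes, median log2 fold change 0.43, camera adjusted p = 3.91e-08), with adjusted p = 0.420 with an estimated correlation. Of these, Cd68 rose (12.4 ± 1.33 CPM in controls, 18.7 ± 1.31 in mutants, adjusted p = 0.0498, SD, n = 3), and 6 were higher and 0 lower adjusted over the list alone. The macrophage median was 0.26 without mutant replicate 5. Erythroid markers were called higher (7 genes, median 1.06, camera adjusted p = 2.32e-06), with adjusted p = 0.420 with an estimated correlation. None of the 7 passed across all genes, and 5 were higher adjusted over the list alone. The beta-globin gene Hbb-bs, which has near-identical copies, stood at 701 ± 119 CPM in controls and 1617 ± 640 in mutants (adjusted p = 0.0874). Glia and Schwann cell markers were called higher (12 genes, median 0.45, camera adjusted p = 0.00166), with adjusted p = 0.420 with an estimated correlation, and 0 passed singly (4 higher and 1 lower adjusted over the list alone). Neutrophil and marrow markers were called lower (8 genes, median -1.02, camera adjusted p = 0.000855), with adjusted p = 0.420 with an estimated correlation, and 0 passed singly or when adjusted over the list alone. The neutrophil median was -0.64 without control replicate 5. These genes were low: the 4 members with the smallest p had means of 0.917 to 3.53 CPM over all 6 libraries. The library levels of the list overlapped between the groups (exact permutation p = 0.2). Endothelium markers were called higher (16 genes, median 0.18, camera adjusted p = 0.0107), with adjusted p = 0.628 with an estimated correlation, as were cartilage markers (11 genes, median 0.20, camera adjusted p = 0.0442), also with adjusted p = 0.628 with an estimated correlation. In both, 0 genes passed singly or adjusted over the list alone. The endothelium call was lost without control replicate 2 (0.249) or mutant replicate 3 (0.0518). The endothelium median was 0.10 without control replicate 2. The cartilage call was lost without control replicate 3 (0.141) or mutant replicate 5 (0.370), and with scaling to library totals (0.106). The cartilage median was 0.32 without control replicate 3, 0.31 without mutant replicate 3, 0.36 without mutant replicate 4 and 0.08 without mutant replicate 5. Interferon response genes were called higher (24 genes, 24 with positive fold changes, median 0.34, camera adjusted p = 0.000126), with adjusted p = 0.5 with an estimated correlation. None of them passed singly, 1 was higher adjusted over the list alone, and the call was lost without mutant replicate 5 (0.0503). The interferon median was 0.52 without control replicate 2 and 0.14 without mutant replicate 5.

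**Figure D3:**
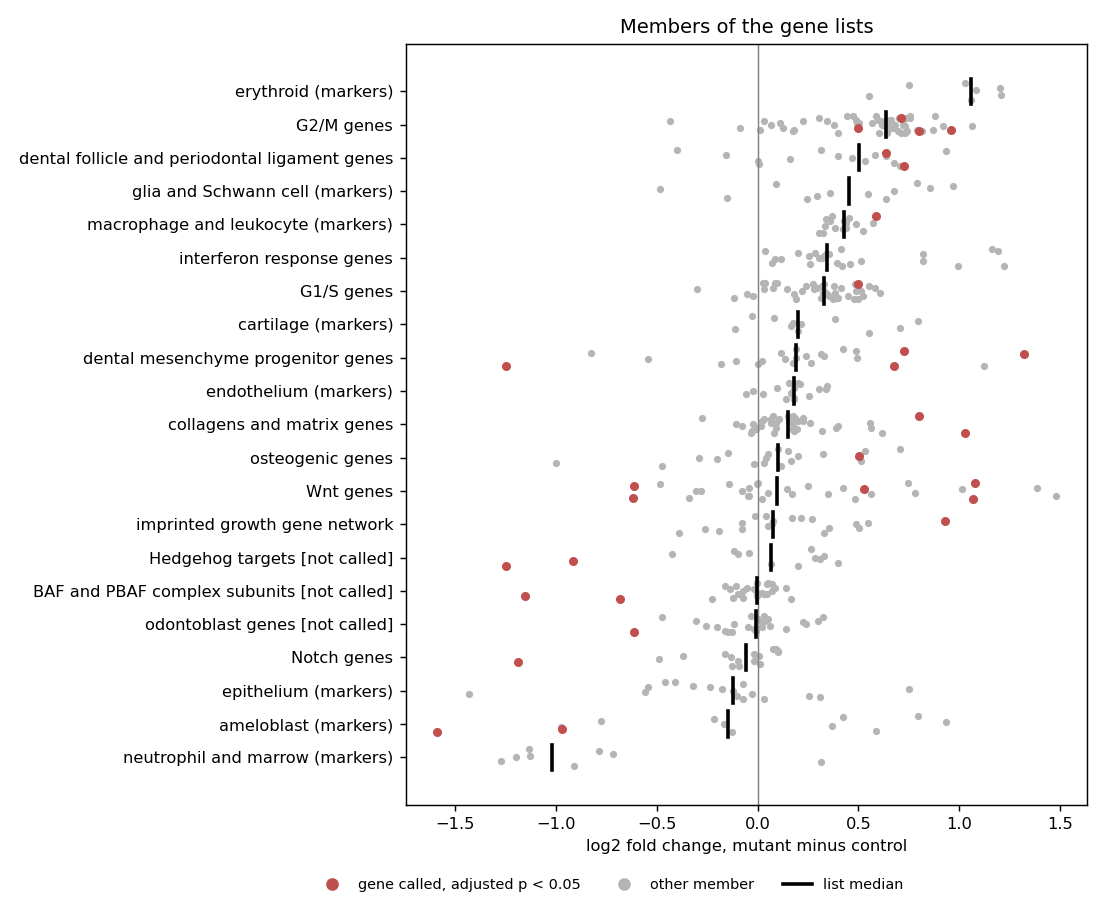
Log2 fold changes (x axis, mutant minus control, TMM scaling) of the members of 21 gene lists, with genes called at an adjusted p under 0.05 in red, other members in grey and the list median as a black bar. Of the lists shown, 18 were called by camera with a preset correlation and 3 were not, and 0 were called with an estimated correlation.

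The remaining lists were not called. Their camera adjusted p values were 0.694 for BMP and TGF-beta genes, 0.703 for FGF and ERK feedback genes, 0.0940 for immediate early and stress genes, 0.596 for ribosomal protein genes and 0.2 for mitochondrial genome genes. They were 0.464 for glycolysis and hypoxia genes, 0.0728 for pericyte and smooth muscle markers, 0.416 for osteoclast markers, 0.322 for skeletal muscle markers and 0.2 for adipocyte markers. The immediate early list was called higher in 3 of the 6 leave-one-out fits, and its median ran from -0.11 to 0.23 over these fits. The pericyte list was called in 2 of the 6, and the mitochondrial, osteoclast and skeletal muscle lists in 1 each. Single members passed in some of these remaining lists. Grem1, a BMP antagonist gene, rose (0.854 ± 0.196 CPM in controls, 2.19 ± 0.0244 in mutants, adjusted p = 0.0465, SD, n = 3), and so did the smooth muscle myosin gene Myh11 (adjusted p = 0.0499). Dusp4, a phosphatase gene of ERK feedback (9.86 ± 3.11 and 3.41 ± 0.38 CPM, adjusted p = 0.0276), fell. In the glycolysis and hypoxia list, Hk2 (adjusted p = 0.0312), Ndrg1 (0.0389) and Car9 (0.0499) fell. In a comparison of the mean log2(CPM + 1) of each list per library, 3 libraries against 3 cannot give an exact permutation p below 0.1 (two-sided). That smallest value was reached by 10 of the 34 lists, among them G2/M genes, follicle genes, progenitor genes, Wnt genes, Notch genes, collagens and macrophage markers. Other lists called by camera had library levels that overlapped between the groups. Their exact p was 0.2 for G1/S, osteogenic, interferon, neutrophil and erythroid genes, 0.3 for imprinted genes, 0.6 for epithelium and 0.7 for ameloblast markers. The smallest adjusted value over the 34 lists was 0.340.

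Transcripts of the sex chromosomes differed between libraries within each group. Xist, which is expressed from the inactive X chromosome, stood at 1019 CPM in control replicate 3, 799 in mutant replicate 3 and 1298 in mutant replicate 5, and at 0.130 to 2.40 CPM in the other 3 libraries. The Y-linked gene Ddx3y stood at 52.3, 62.6 and 54.1 CPM in control replicates 2 and 5 and mutant replicate 4, and at 0 to 0.176 CPM in the rest. Females were thus 1 of 3 libraries in the control group and 2 of 3 in the mutant group. With the Xist level as a term in the model, added after the data were seen, 32 genes were higher and 59 lower. With the erythroid marker level as a term, also added later, 2 were higher and 7 lower. Besides the G1/S list, that term ended the calls of the progenitor (camera adjusted p = 0.0976), imprinted (0.0976), osteogenic (0.195), Wnt (0.183), interferon (0.169), ameloblast (0.0937), epithelium (0.871), neutrophil (0.0899), cartilage (0.167) and erythroid (0.486) lists. These losses differ in kind: with the term the imprinted median went from 0.07 to 0.11 and the neutrophil median from -1.02 to -0.80, while the ameloblast median went from -0.15 to 0.10. The calls of the G2/M, follicle, collagen, Notch, endothelium, macrophage and glia lists were kept, and Hedgehog targets were called lower (0.0264) and immediate early genes higher (0.00122).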

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

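The terms for Xist, epithelial and erythroid level and the fit without abundant transcripts were chosen after the results were seen, and the other alternatives were planned. Under TMM, 114 genes were higher and 208 lower, and 14 gene lists were called higher and 4 lower. The calls numbered 411 higher and 109 lower with library totals only, 360 and 493 with DESeq2, and 364 and 455 with the edgeR likelihood ratio test. At an adjusted p under 0.1, genes higher in mutant numbered 272 and genes lower in mutant 400, against 43 and 63 with a log2 fold of at least 1. With the Xist term they were 32 and 59, and with the erythroid term 2 and 7. The cause was not tested for these differences, apart from the thresholds, which change the count by construction. DESeq2 called 320 of the 322 genes. All 322 kept their sign in every alternative that tested them.

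With a replicate block on the numbers shared between groups, 19 genes were higher and 71 lower, and Arid1a had a log2 fold change of -0.70 (adjusted p = 0.0769). Over the other choices of scaling, filter and test set in advance, the Arid1a log2 fold change ran from -0.68 to -0.48 and its adjusted p from 9.99e-13 to 0.0378. Libraries that share a number did not go together: the correlation of their deviations was 0.20 for replicate 3 and -0.15 for replicate 5. The block ended the osteogenic (camera adjusted p = 0.405), Wnt (0.11) and endothelium (0.458) calls. It also called mitochondrial genome genes lower (median -0.25, camera adjusted p = 0.00204), which the main test did not. It uses up residual degrees of freedom.

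With 1 library left out, calls ranged from 1 to 105 higher and from 10 to 138 lower. Lists called higher ranged from 12 to 15 and lists called lower from 2 to 5. The Arid1a log2 fold change ranged from -0.71 to -0.64, and its adjusted p was above 0.05 without control replicate 2 (0.0506) or control replicate 3 (0.0529). These fits have fewer samples.

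With the correlation estimated from the data, 0 lists were called higher and 0 lower. With fry, 1 was called higher and 0 lower. With the erythroid term, 7 were higher and 2 lower, and the epithelium list changed from lower to higher without passing (camera adjusted p = 0.871). Its adjusted p over the leave-one-out fits ran up to 0.644. The cause was not tested. Of 2292 values of the named genes under the alternatives, 293 lost the call, 42 gained it and 1957 stayed on their side of the threshold, of which 40 changed sign without passing in either fit. None of the called values reversed. In the self-test at this depth, 28.1% of 1.5-fold differences were called, so smaller differences are often missed.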

Other observations

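The tests of Gli1, of enamel stage and of cell dilution were chosen after the results were seen, as were the Xist and erythroid terms themselves, though what those terms would show was written down before they were run. The count over other splits was planned. Of the 10 splits of the 6 libraries into 3 against 3, 1 gave as many calls as the real one, which is the real split itself. The real split gave 322 calls and the highest other gave 5. With 10 splits the share is never under 0.1, which is too few for a share under 0.05.

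Of the secretory enamel genes Amelx, Ambn, Enam and Mmp20, grouped after their values were seen, only Amelx and Mmp20 passed, and the Amelx call was lost in all 6 leave-one-out fits. Their median log2 fold change was -0.97 (exact permutation p = 0.1 for the mean level, the smallest possible). Across the whole ameloblast list of 12 genes, 7 had negative and 5 had positive fold changes. The mean level of that list, which was fixed in advance, overlapped between the groups (exact permutation p = 0.7). Fewer enamel organ cells of every kind would lower epithelial markers alike. The epithelial median was -0.12, a gap of 0.848 to the secretory median, against an SD of 0.460 of the epithelial genes. That SD is a spread between genes, not between libraries. With 1 library left out, the epithelial median ran from -0.32 to -0.01. Because the secretory genes were grouped after their values were seen, the gap cannot decide this explanation. Sex as the whole cause is argued against by a median of -0.94 with an Xist term. A different share of secretory and later-stage ameloblasts in the dissected pieces stays open: the level of secretory minus later-stage genes differed by -1.61 between groups (exact permutation p = 0.2). It is confounded with an effect of genotype on enamel cells.

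G2/M genes were called higher in the mutants, with a median log2 fold change of 0.64. Before scaling, less enamel RNA would raise all other cell types alike. TMM scaling takes out most of a rise shared by most genes. The median log2 fold change of all tested genes was 0.01 with TMM and 0.21 with library totals. The G2/M median was 0.64 with TMM and 0.83 with library totals. The median of 51 endothelium, pericyte, glia and cartilage markers was lower than that of the G2/M genes by 0.46, against an SD of 0.34 of these markers. That SD is a spread between genes, not between libraries, and the estimated inter-gene correlation was 0.64 for the G2/M genes. The gap between these lists therefore cannot decide this explanation, while the medians of all genes argue against it as the whole cause. Other cell types moved apart, with medians of 0.43 for macrophage, 1.06 for erythroid and -1.02 for neutrophil markers. The library levels of the erythroid and neutrophil lists overlapped between the groups (exact permutation p = 0.2 for both), and the neutrophil genes were low. Sex as the cause is argued against by a G2/M median of 0.66 with an Xist term. With the erythroid level as a term it was 0.33, so more blood cells in the mutant pieces may account for part of the difference and stay open, as does a loss of cell cycle arrest after Arid1a deletion.

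Gli1 was lower in the mutants, with a 95% interval of the log2 fold change from -1.52 to -0.98. The interval includes -1, so a CreER insertion that removes 1 of 2 Gli1 alleles could account for the difference. The labels do not state how the CreER allele was made. A lower Hedgehog response in general also stays open, since the other 12 tested targets had a median of 0.13 and went both ways.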
